A study of Homo sapiens with 18 samples.

How the data were processed

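The series holds 18 samples of ECV304 cells on Affymetrix Human Gene 1.0 ST arrays. The deposited values are log2 signals per transcript cluster, which the authors made by RMA (background correction, quantile normalization and summary) in Affymetrix Expression Console, whose version the labels do not give. Which arrays were normalized together is not stated, and the genome build of the array's annotation is not stated, so no coordinates are given. The table has 28869 transcript clusters, of which 21062 carry a gene annotation, 19310 a single gene symbol, 1752 several symbols and 7807 none; 19279 of those with a single symbol matched a RefSeq gene by gene ID. For arrays there is no read depth, and their number limits the precision.

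Samples were grouped by treatment (IL-1β alone, or IL-1β with aminaphtone) and time (1, 3 or 6 h), 3 per group. Annotated transcript clusters with a mean log2 signal above the 25th percentile (6.193) were tested, 15796 in all, of which 14481 have a single symbol, for 13805 genes. A linear model with 1 mean per group was fitted to all 18 arrays in limma 3.58.1 (R 4.3.3), with 12 residual degrees of freedom and 4.814 prior degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over the transcript clusters tested, with a threshold of 0.05. The comparisons were aminaphtone against control at each time and averaged over the times, the interaction of treatment and time, and the differences between control times. All tests are two-sided. The groups, comparisons, filter, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined.

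The rule for named genes took, per comparison, the 12 largest rises and the 12 largest falls past the threshold whose groups do not overlap (for the average, the same direction at all 3 times), or 5 and 5 by p where none passed, and the 10 smallest p-values of the interaction. It added up to 4 members of each list by p where a member passed and up to 3 where none did, and 17 genes of inflammation, vascular function and oxidative stress fixed in advance. Of these, VCAM1, CYP1A1 and CYP1B1 lay under the filter (mean log2 5.67, 5.87 and 5.88), and 1 other gene was not analysed here. A pair of groups of 3 does not overlap by chance in 10% of genes. Where a gene has several transcript clusters, lists used the one with the highest mean, and genes whose transcript clusters disagreed in a comparison were not named.

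The gene lists were 26 lists of named genes and 6 made from symbol patterns, 1 of which, the mitochondrially encoded genes, had no member on the arrays. Each was tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists. Counts of list members were made over all genes tested and adjusted over the list alone. Exact permutation tests of list means between 3 and 3 arrays cannot go below 0.1.

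Whether replicate numbers pair the arrays was checked by correlating the deviations of each array from its group mean. At 1 h treated and control arrays of equal number correlated at 0.746, 0.411 and 0.322. Each array went best with its own number (6 of 6). So did control arrays at 1 and 3 h (0.313, 0.359 and 0.258, 6 of 6). Both sets were taken as pairs, which the labels do not give. In these groups the replicates rise in the order 1, 3 and 2 on the main residual gradient described below. A shared number and a shared order along that gradient cannot be told apart here. At 3 h (-0.106, 0.519 and -0.0106, 2 of 6), at 6 h (0.456, -0.0862 and 0.711, 3 of 6), and between the 6 h controls and those at 1 h (-0.444, 0.327 and -0.216, 1 of 6) or 3 h (-0.23, -0.204 and 0.0157, 0 of 6), arrays share a number without such a relation. For both sets of pairs the counts with the number as a block stand beside the unblocked ones. At 1 h they come from a block within each of the 3 times, so 3 and 6 h arrays of equal number were blocked too. For the controls they come from a common effect of the number over all 6 groups. Values of genes and lists are unblocked where no blocked value is given.

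The calculation was tested on simulated data of the same size, with 200 changed transcript clusters and no shared gradient between arrays. Transcript clusters were drawn independently of each other, each with the same spread in every group. At log2 differences of 0.5, 1 and 2 it recovered 23.9%, 83.6% and 100% at 1 h, 19.4%, 83.6% and 100% at 3 h, 26.9%, 80.6% and 98.5% at 6 h, 86.6%, 100% and 100% for the average, and 4.48%, 56.7% and 97% for the interaction. For the controls it recovered 26.9%, 91% and 98.5% between 1 and 3 h, 28.4%, 91% and 100% between 1 and 6 h, and 40.3%, 86.6% and 100% between 3 and 6 h. The false calls among unchanged transcript clusters numbered 3, 5 and 12 at 1, 3 and 6 h, 13 for the average, 5 for the interaction, and 7, 7 and 8 in the controls in the order above. Camera at the preset correlation called a simulated list of 31 genes shifted by -0.4 and did not call an unshifted one. Since the simulated genes were independent, this does not test camera on correlated genes.

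The alternatives chosen in advance were no filter on the mean, a filter at the 50th percentile (7.534), all transcript clusters, quantile normalization applied again, arrays centred on their medians, array weights, a trended robust variance, a block for the replicate number, a block within times, only the arrays compared, a plain test per gene, a threshold of at least 1.5-fold, and each array left out in turn. Added after the data were seen were a fit without the 1 h arrays, one without both control 1 h replicates 2 and 3, one with the main residual gradient as a covariate, and one with identical rows counted once. Transcript clusters with several symbols stayed in the counts and were not named. Transcript clusters without an annotation were tested apart. Raw array files were not used here.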

Results

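Gene expression was measured on 18 Affymetrix Human Gene 1.0 ST arrays, 1 per sample, in ECV304 cells, an established human line with endothelial and epithelial characteristics. Every sample received interleukin-1β (IL-1β), a pro-inflammatory cytokine, at 100 IU/ml. The treated groups also received aminaphtone, a naphthohydroquinone derivative used for capillary disorders, at 6 µg/ml, and the control groups received medium in its place. RNA was taken at 1, 3 and 6 h, with 3 arrays in each of the 6 groups, labelled as independent replicates. Every sample is also labelled as serum-starved, for the same length of time and at the same reduced serum level. No cells without IL-1β were included, so a difference between control times describes the time since IL-1β was added. Such a difference cannot separate an effect of IL-1β from effects of the serum starvation or of time in culture. The log2 signal ran from 1.85 to 14.25 and the array medians from 6.926 to 7.055. The number of arrays limits the precision of each value. The p-values measure the spread between these samples as far as the labels describe them, taken per gene as 1 spread over all groups. The 1 h control arrays differed more among themselves than those of any other group, with correlations across transcript clusters of 0.889 to 0.963 against at least 0.970 in the other groups. The shared spread can therefore be too small for the 1 h comparisons and too large for others. With only the arrays compared in the fit, which also has fewer degrees of freedom, 14 transcript clusters past the threshold became 0 at 1 h. At 6 h 17 became 70.

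**Figure D1:**
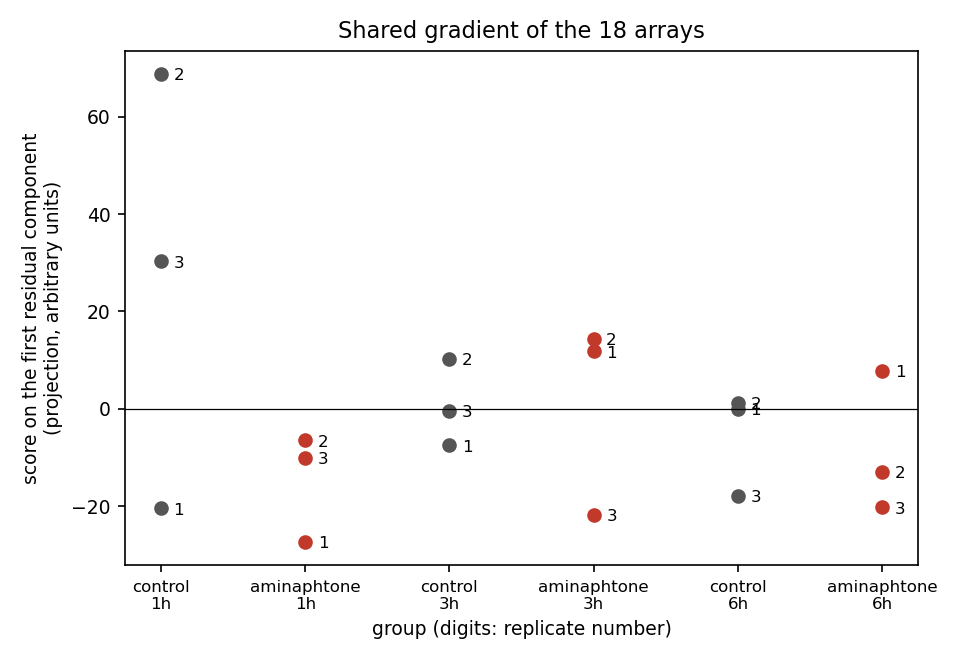
Score of each array (y axis, arbitrary units) on the first component of the residuals of the model, by group (x axis), with 1 point per array and its replicate number. The 1 h control arrays lie at -20.4, 68.7 and 30.3, and this component holds 59.9% of the residual variance.

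The control arrays followed the cells after IL-1β was added. Between 1 and 3 h the immediate early genes, which answer stimuli transiently, fell. Of the 29 measured members, 22 were lower over all genes tested, and 25 adjusted over the list alone. NR4A2 and NR4A1, orphan nuclear receptors, were 19.3-fold (log2 difference -4.27, SE 0.185, n = 3 per group, adjusted p = 2.78e-10) and 15.5-fold lower (log2 -3.96, SE 0.195, adjusted p = 1.33e-09). EGR1, a zinc finger transcription factor, was 8.32-fold lower (log2 -3.06, SE 0.343, adjusted p = 2.36e-05). PRDM1, a transcriptional repressor, was 5.51-fold lower. Cytokine and chemokine genes rose over the same interval, 11 of 22 over all genes tested, against 13 higher and 2 lower adjusted over the list alone. CCL5, a chemokine for T cells and monocytes, was 9.36-fold higher (log2 3.23, SE 0.264, adjusted p = 9.13e-07). IL1B, the gene of IL-1β itself, was 6.8-fold higher (log2 2.76, SE 0.258, adjusted p = 3.42e-06). Of the NF-κB feedback and target genes, 14 of 26 were higher and 4 lower (15 and 6 adjusted over the list alone), with TRAF1 2.77-fold and IRAK2 3.39-fold higher. Of the adhesion molecules, 6 of 16 were higher (8 higher and 1 lower adjusted over the list alone), among them ITGA2, an integrin subunit, 5.38-fold, and CD44 2.61-fold.

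By camera, which sets a list against all other genes, the immediate early list was lower between 1 and 3 h (median log2 difference -1.19, adjusted p = 4.25e-23; adjusted p = 0.168 with an estimated correlation). The cytokine list was higher (median 0.53, adjusted p = 2.29e-07; adjusted p = 0.431 with an estimated correlation). So was the NF-κB list (median 0.52, adjusted p = 0.00026; adjusted p = 0.431 with an estimated correlation). The adhesion list was higher too (median 0.47, adjusted p = 0.0012; adjusted p = 0.19 with an estimated correlation). By fry, which tests whether a list's genes move, on balance, one way and makes no comparison with other genes, the immediate early (adjusted p = 8.2e-06) and cytokine lists (adjusted p = 0.00244) passed. In all, limma found 759 transcript clusters higher and 1261 lower of the 15796 tested. With the replicate number as a block over all groups it found 916 higher and 1376 lower. The number is taken here to pair these arrays, but arrays of equal number did not consistently go together in other groups. The unblocked total of 2020 became 5719 without control 1 h replicate 1, 1289 without control 1 h replicate 3, 988 without control 3 h replicate 1 and 1217 without control 3 h replicate 3. It was 228 with only the arrays compared in the fit, and no call was left by a plain test per gene.

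By 6 h, matrix metalloproteinase genes were among the largest rises over the 1 h controls. MMP1, a collagenase, was 14.6-fold higher (log2 3.87, SE 0.218, n = 3 per group, adjusted p = 7.87e-09). MMP3, a stromelysin, was 9.18-fold higher, and MMP10, another stromelysin, 8.74-fold. NR4A1 was 22.9-fold lower (log2 -4.52, SE 0.195, adjusted p = 1.88e-10). Of the 17 cholesterol synthesis genes, 12 were lower over all genes tested and 14 adjusted over the list alone (median log2 -1.04), among them HMGCS1, an enzyme of the mevalonate pathway, 4.06-fold. Of the 29 immediate early genes, 25 were lower over all genes tested. The cholesterol list (adjusted p = 1.04e-07; adjusted p = 0.0992 with an estimated correlation) and the immediate early list (adjusted p = 6.85e-22; adjusted p = 0.0992 with an estimated correlation) passed camera. Between 1 and 6 h 1783 transcript clusters were higher and 2402 lower, and the total of 4185 became 7083 without control 1 h replicate 1 and 2586 without control 6 h replicate 3. It was 1088 with only the arrays compared in the fit and 40 by a plain test per gene.

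Between 3 and 6 h in the controls, genes of the hypoxia and glycolysis list rose: 7 of 31 over all genes tested, against 16 higher and 1 lower adjusted over the list alone. BNIP3, a mitophagy receptor, was 2.62-fold higher (log2 1.39, SE 0.129, n = 3 per group, adjusted p = 4.74e-05). PFKFB4, which sets the level of a glycolytic activator, was 3.12-fold higher (log2 1.64, SE 0.161, adjusted p = 6.92e-05). STC2, a stanniocalcin, was 3.84-fold higher (adjusted p = 2.55e-05) and MMP1 4.37-fold higher (adjusted p = 9.42e-05). All 17 cholesterol synthesis genes had negative differences. IDI1, an isoprenoid isomerase, passed over all genes tested (3.11-fold lower, adjusted p = 0.00082), and 8 genes adjusted over the list alone. The hypoxia and glycolysis list (median log2 0.30, adjusted p = 3.57e-14; 0.0319 with an estimated correlation) passed camera in both forms. So did the cholesterol list (median -0.51, adjusted p = 4.42e-13; 0.027 with an estimated correlation) and the S phase list (median -0.30, adjusted p = 3.37e-08; 0.0361 with an estimated correlation). No S phase gene passed over all genes tested, and 5 were lower and 1 higher adjusted over the list alone. NF-κB target genes went down as a list, with 2 of 26 lower over all genes tested and 8 adjusted over the list alone (adjusted p = 4.37e-07; adjusted p = 0.218 with an estimated correlation). REL, an NF-κB subunit, was 3.32-fold lower (adjusted p = 0.0434), and IRF1, an interferon regulatory factor, 2.26-fold lower (adjusted p = 0.0277).

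The 3 to 6 h comparison called 81 transcript clusters, 55 higher and 26 lower. That total became 235 without control 1 h replicate 1, 309 without control 1 h replicate 2, 163 and 18 without control 3 h replicates 1 and 2, and 16, 48 and 29 without control 6 h replicates 1, 2 and 3. It was 166 with only the arrays compared in the fit, and no call was left by a plain test per gene. BNIP3, PFKFB4, STC2, MMP1 and IDI1 were among the 13 of 30 named and called genes that passed without every array in turn, whereas REL and IRF1 reached adjusted p = 0.244 and 0.215 in the least favourable case.

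**Figure D2:**
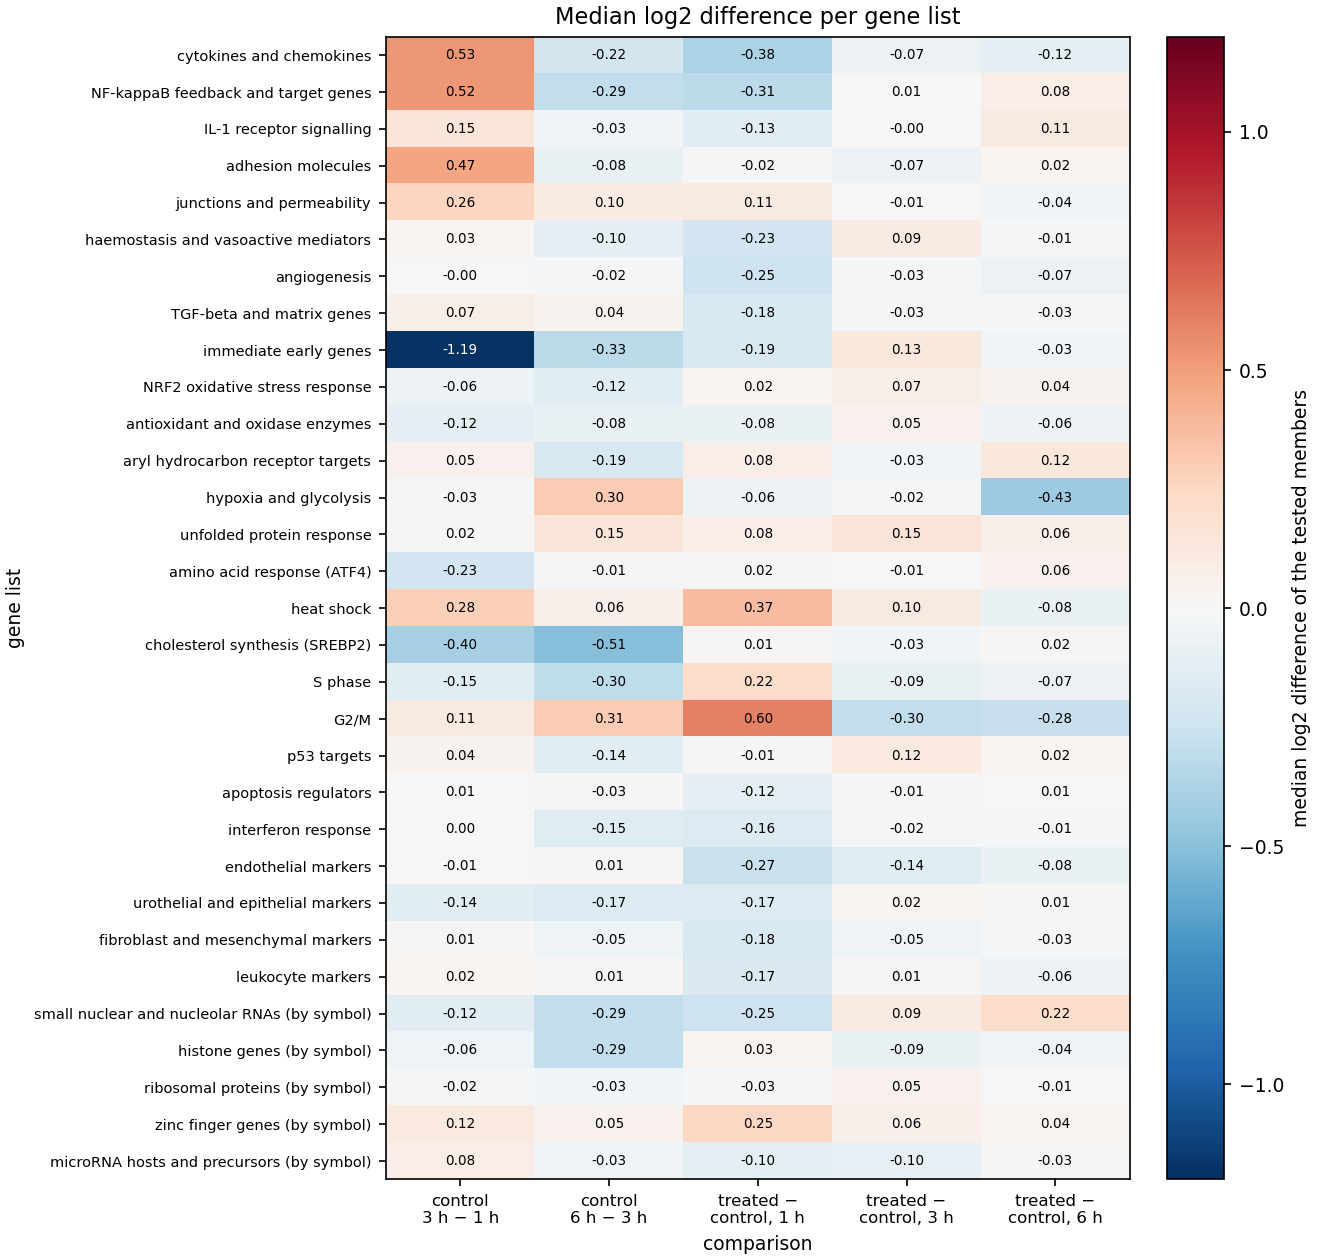
Median log2 difference (colour and printed value) of the measured members of each gene list (y axis) in 5 comparisons (x axis), 3 arrays per group. The immediate early list stands at -1.19 between 1 and 3 h in the controls, the G2/M list at 0.60 for treated minus control at 1 h, and the hypoxia and glycolysis list at -0.43 at 6 h.

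The comparison at 1 h asked which transcripts differed with aminaphtone early after IL-1β. MYLIP, an E3 ubiquitin ligase that acts on the LDL receptor, was 2.84-fold higher (log2 1.5, SE 0.144; 8.92 ± 0.135 against 7.42 ± 0.271, SD, n = 3 each; adjusted p = 7.49e-05). FOS, a component of the transcription factor AP-1, was 2.13-fold higher (log2 1.09, SE 0.146; 10.9 ± 0.139 against 9.78 ± 0.139; adjusted p = 0.00271). PRDM1, which falls with time in the controls, was 2.47-fold lower (log2 -1.30, SE 0.122; 8.09 ± 0.201 against 9.39 ± 0.233; adjusted p = 7.49e-05). MIDEAS, a subunit of a histone deacetylase complex, was 1.86-fold lower (log2 -0.89, SE 0.118, adjusted p = 0.00271). These 4 genes passed without every array in turn, with a highest adjusted p of 0.0354, and lost their calls, as did the other genes called at 1 h, with only the 6 arrays compared in the fit and by a plain test per gene. S100A3, a calcium-binding protein of the S100 family, was 2.37-fold lower (adjusted p = 0.0136). TICAM1, an adaptor of Toll-like receptors, was 1.79-fold lower (adjusted p = 0.025), and RIPK4 and IRF2BP2 1.79-fold and 1.65-fold lower (both adjusted p = 0.034). DIPK2A was 1.54-fold higher (adjusted p = 0.0354). With 1 of the 18 arrays left out in turn, the calls held in 14 fits for S100A3 and TICAM1, 8 for IRF2BP2, 7 for RIPK4 and 4 for DIPK2A. The highest adjusted p-values were 0.128, 0.244, 0.289, 0.289 and 0.244. IRF2BP2, RIPK4 and DIPK2A also lost their calls with a trended, robust variance, and DIPK2A with each array centred on its median. IRF2BP2 and RIPK4 lost theirs with the array gradient as a covariate too, an alternative added after the data were seen.

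At 1 h limma called 14 transcript clusters, 8 higher and 6 lower with aminaphtone, or 6 higher and 8 lower with each array centred on its median, which moves the median of all transcript clusters from -0.0967 to -0.157. At an unadjusted p under 0.05 there were 4858, or 30.8% of those tested. At such a share, genes can pass when adjusted over a list alone without a change particular to that list. Replicate numbers were taken to pair treated and control arrays at 1 h, which the labels do not state. The deviations of the arrays from their group means correlated at 0.746, 0.411 and 0.322 for equal numbers. Blocked values at 1 h rest on these correlations. With the pairs as a block, 1715 transcript clusters were higher and 750 lower, 2465 in all. That fit has 9 blocks and 6 residual degrees of freedom. It blocks the 3 and 6 h arrays by number as well, although these did not consistently go together. The unblocked 14 became 8516 without control 1 h replicate 1, 8 without control 1 h replicate 3, 6 and 7 without aminaphtone 1 h replicates 1 and 2, 25 without control 3 h replicate 2 and 8 without aminaphtone 6 h replicate 2. Without both control 1 h replicates 2 and 3, an alternative added after the data were seen, 6 were called; that fit leaves the control group at 1 h with 1 array, whose variance is taken from the other groups.

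Cell division genes had higher values with aminaphtone at 1 h. None of the 26 measured G2/M genes passed over all genes tested, and 17 were higher adjusted over the list alone (median log2 0.60, camera adjusted p = 8.49e-08; adjusted p = 0.348 with an estimated correlation; fry adjusted p = 0.021). BUB1, a spindle checkpoint kinase, had a log2 difference of 0.95 (adjusted p = 0.124, or 0.0295 with pairs as a block), and NEK2, a centrosomal kinase, one of 0.83 (adjusted p = 0.122, or 0.0172 with the block). None of 26 S phase genes passed over all genes tested, and 9 were higher adjusted over the list alone (median 0.22, adjusted p = 0.000889; adjusted p = 0.348 with an estimated correlation), with RRM2, a subunit of ribonucleotide reductase, at 0.67 (adjusted p = 0.0865, or 0.0172 with the block). The S phase call was lost without control 1 h replicate 1 (adjusted p = 0.0808), and the G2/M call held without every array. With the array gradient as a covariate, the mean log2 difference of the G2/M list went from 0.591 (SE 0.158) to 0.341 (SE 0.14). That of the S phase list went from 0.299 (SE 0.0544) to 0.288 (SE 0.0675). Of 16 heat shock genes, none passed over all genes tested, and 7 were higher and 1 lower adjusted over the list alone (median 0.37, adjusted p = 0.0337; adjusted p = 0.348 with an estimated correlation). The heat shock list reached adjusted p = 0.0532 with pairs as a block, 0.101 without control 1 h replicate 1 and 0.0614 without aminaphtone 1 h replicate 2.

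Cytokine and chemokine genes had lower values with aminaphtone at 1 h, with negative differences in 20 of 22. None passed over all genes tested, and 8 were lower adjusted over the list alone (median log2 -0.38, camera adjusted p = 0.000979; adjusted p = 0.773 with an estimated correlation; fry adjusted p = 0.0766, or 0.00786 with pairs as a block). CX3CL1, a membrane-anchored chemokine, stood at -0.95 (adjusted p = 0.139, or 0.0172 with the block), and CCL2, a monocyte chemokine, at -0.60 (adjusted p = 0.139, or 0.0228 with the block). IL6 stood at -0.43 (adjusted p = 0.139, or 0.0315 with the block), and CXCL8 at 0.03 (adjusted p = 0.872). Of 26 NF-κB feedback and target genes none passed over all genes tested and 9 were lower adjusted over the list alone (median -0.31, adjusted p = 0.0206; adjusted p = 0.793 with an estimated correlation). BCL3, an atypical inhibitor of NF-κB, stood at -0.99 (adjusted p = 0.0682, or 0.0081 with the block) and TRAF1 at -0.76 (adjusted p = 0.0865, or 0.0254 with the block). The NF-κB call was lost without control 1 h replicate 1 (adjusted p = 0.133), control 1 h replicate 3 (0.104) or aminaphtone 1 h replicate 2 (0.107), and the cytokine call held without every array. With the array gradient as a covariate, the mean log2 difference of the cytokine list went from -0.35 (SE 0.126) to -0.256 (SE 0.148). Of 23 haemostasis and vasoactive genes none passed over all genes tested and 4 were lower adjusted over the list alone (median -0.23, adjusted p = 0.0358; adjusted p = 0.793 with an estimated correlation). EDN1, the gene of the vasoconstrictor endothelin-1, stood at -0.84 (adjusted p = 0.0865, or 0.0188 with the block). The haemostasis call was lost without control 1 h replicate 1 (adjusted p = 0.133), control 1 h replicate 3 (0.125), aminaphtone 1 h replicate 1 (0.0544) or aminaphtone 1 h replicate 2 (0.107), and with the stricter filter (0.0649). ICAM1, an adhesion molecule, stood at -0.38 (adjusted p = 0.139, or 0.0396 with the block), and HMOX1, haem oxygenase, at -0.59 (adjusted p = 0.133, or 0.0361 with the block). On the first residual component the 1 h groups compared here scored 26.2 ± 44.7 (control) and -14.6 ± 11.1 (aminaphtone; mean ± SD, n = 3 arrays each).

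Of the genes called at 3 h, the largest difference with aminaphtone was in TNFSF18, the ligand of the T cell receptor GITR, which was 4.24-fold lower (log2 -2.09, SE 0.316; 7.21 ± 0.237 against 9.29 ± 0.349, SD, n = 3 each; adjusted p = 0.0359). CCL22, a ligand of the chemokine receptor CCR4, was 2.2-fold lower (log2 -1.14, SE 0.184; 7.27 ± 0.22 against 8.41 ± 0.383; adjusted p = 0.0359). OXTR, the oxytocin receptor, was 1.62-fold lower (adjusted p = 0.0359). CNNM4, a magnesium transporter, was 2-fold higher (log2 1.00, SE 0.149, adjusted p = 0.0359), and KHDRBS3, an RNA-binding protein, 1.57-fold higher (adjusted p = 0.0359). MERTK, a receptor tyrosine kinase, was 1.79-fold higher (8.76 ± 0.0377 against 7.91 ± 0.0609; adjusted p = 0.0489). Just outside the threshold, EDN1 had a log2 difference of -0.95 (adjusted p = 0.0811) and TGFB2, a transforming growth factor, one of -1.10 (adjusted p = 0.0806). IL1B stood at -0.94 (adjusted p = 0.378), and IL6, CXCL8, CCL2 and ICAM1 lay between -0.14 and 0.15 (adjusted p = 0.87 to 0.944).

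These 6 genes, 3 higher and 3 lower, were all that limma called at 3 h, with 1027 transcript clusters at an unadjusted p under 0.05. None of the 6 kept its call without every array, and each reached adjusted p = 0.262 in the least favourable case. All but 1 lost their calls with only the arrays compared in the fit, and all by a plain test per gene. Among 8 other alternatives, MERTK lost its call with no filter, quantile normalization applied again, a trended, robust variance and the block within times. KHDRBS3 lost its call with arrays centred on their medians, a trended, robust variance and the block within times, and OXTR with the last 2 of these. The count was 21 and 48 without control 1 h replicates 1 and 2, 3 without control 6 h replicate 3, and 1 without control 3 h replicate 1 or control 6 h replicate 2. It was 0 without aminaphtone 1 h replicate 1 or 2, control 3 h replicate 2 or 3, control 6 h replicate 1, or any 1 of the aminaphtone arrays at 3 or 6 h.

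Among the lists at 3 h, G2/M genes had negative differences in 25 of 26, the opposite sign from 1 h, and none passed over all genes tested or adjusted over the list alone (median log2 -0.30, camera adjusted p = 2.17e-06; adjusted p = 0.783 with an estimated correlation; fry adjusted p = 0.542). The unfolded protein response list was higher, with positive differences in 16 of 19 and 1 gene higher adjusted over the list alone (median 0.15, adjusted p = 0.00356; adjusted p = 0.406 with an estimated correlation). HERPUD1, which acts in protein degradation at the endoplasmic reticulum, stood at 0.60 (adjusted p = 0.0932). That call was lost without control 3 h replicate 2 (adjusted p = 0.0512). The cytokine list was lower, with 3 genes lower and 1 higher adjusted over the list alone (median -0.07, adjusted p = 0.00249; adjusted p = 0.855 with an estimated correlation), and lost its call without control 3 h replicate 2 (adjusted p = 0.314) or aminaphtone 3 h replicate 3 (0.057).

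At 6 h every transcript cluster called in the fit of all arrays was lower with aminaphtone, and 5 belong to the hypoxia and glycolysis list. BNIP3 was 2.54-fold lower (log2 -1.34, SE 0.129; 10.6 ± 0.209 against 12 ± 0.162, SD, n = 3 each; adjusted p = 0.000159). PFKFB4 was 2.67-fold lower (log2 -1.42, SE 0.161; 7.29 ± 0.126 against 8.71 ± 0.229; adjusted p = 0.000851). HK2, a hexokinase, was 2.25-fold lower (log2 -1.17, SE 0.176, adjusted p = 0.0133). PDK1, a kinase that restrains pyruvate dehydrogenase, was 2.37-fold lower (log2 -1.24, SE 0.204, adjusted p = 0.0223), and ENO2, an enolase, 2.31-fold lower (adjusted p = 0.0355). HILPDA, a lipid droplet protein induced by hypoxia, was 2.09-fold lower (adjusted p = 0.019). Of the 31 genes of the hypoxia and glycolysis list, 5 fell over all genes tested, 18 adjusted over the list alone, and 27 had negative differences (median log2 -0.43). The list passed camera (adjusted p = 2.26e-33), camera with an estimated correlation (adjusted p = 0.00157) and fry (adjusted p = 0.000238), and without each array in turn camera gave 1.7e-41 to 2.44e-25. VEGFA, a hypoxia-responsive growth factor, stood at -0.51 (adjusted p = 0.947).

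**Figure D3:**
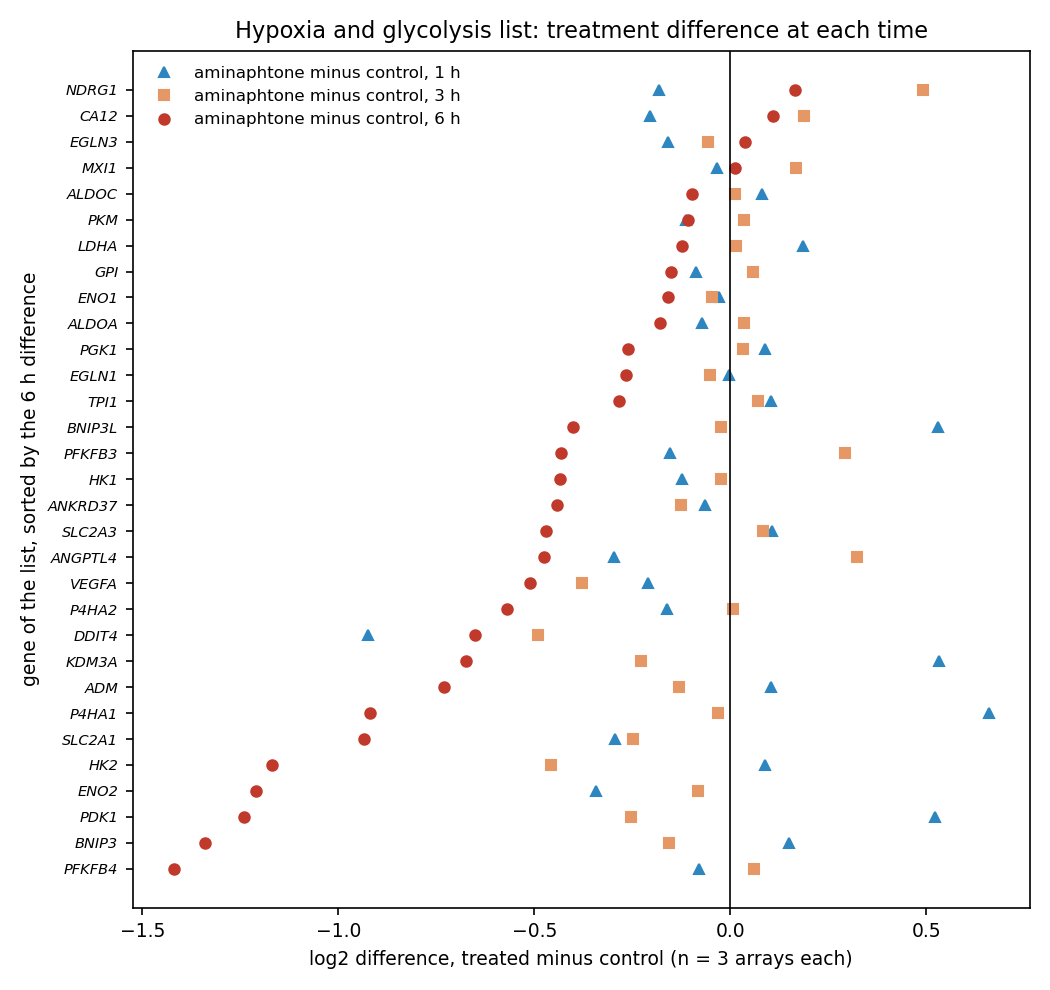
Log2 difference, treated minus control (x axis), of each measured gene of the hypoxia and glycolysis list (y axis, sorted by the 6 h difference) at 1, 3 and 6 h, 3 arrays per group. At 6 h 27 of the 31 genes lie below 0, with BNIP3 at -1.34 and PFKFB4 at -1.42.

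At 6 h TNFSF18 was also 3.41-fold lower (log2 -1.77, SE 0.316, n = 3 each, adjusted p = 0.0438), EBI3, a subunit of interleukin-27, 2.06-fold lower (adjusted p = 0.0448), and CCL22 1.99-fold lower (adjusted p = 0.0457). EDN1 was 1.97-fold lower (log2 -0.98, SE 0.178; 9.58 ± 0.0841 against 10.6 ± 0.161; adjusted p = 0.0448). MMP10 was 2.37-fold lower (log2 -1.24, SE 0.171, adjusted p = 0.00562), and the stanniocalcins STC1 and STC2 were 2.01-fold (adjusted p = 0.0448) and 1.93-fold lower (adjusted p = 0.0355). EVA1A (log2 -0.80, adjusted p = 0.00562), DKK1, a Wnt antagonist (log2 -0.95, adjusted p = 0.019), DIPK2A (log2 -0.69, adjusted p = 0.0209) and PODXL (log2 -0.76, adjusted p = 0.0457) complete the 17, and these 4 were chosen after their values were seen. SELE, the gene of E-selectin, stood at 0.92 (adjusted p = 0.0503), and IL6, CXCL8, CCL2 and ICAM1 lay between -0.15 and 0.16 (each adjusted p = 1). The TGF-β and matrix list had 1 of 36 lower over all genes tested and 4 adjusted over the list alone (median -0.03, mean -0.15, camera adjusted p = 0.0109; adjusted p = 0.686 with an estimated correlation), a call lost without control 6 h replicate 3 (adjusted p = 0.0859), with the stricter filter (0.992) and with the array gradient as a covariate (0.115). G2/M genes again had negative differences in 25 of 26 (median -0.28, adjusted p = 7.7e-06; adjusted p = 0.686 with an estimated correlation).

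At 6 h limma called 17 transcript clusters, all lower, with 620 at an unadjusted p under 0.05. The direction was not uniform in every alternative: 24 were higher and 46 lower with only the arrays compared, 2 and 24 with a block within times, and 32 and 101 with the array gradient as a covariate. A plain test per gene kept none of the 17 calls and made 1 other. Of the 13 named and called genes, BNIP3 and PFKFB4 passed without every array in turn, and the others reached adjusted p = 0.0695 (MMP10) to 0.333 (CCL22) in the least favourable case. EDN1, EBI3 and STC1 also lost their calls with quantile normalization applied again and with a block for the replicate number, and CCL22 with that block. The count was 38 without control 1 h replicate 1 or 2, 9 without aminaphtone 1 h replicate 1 or 2, 11 without aminaphtone 1 h replicate 3, and 10 without control 3 h replicate 3 or aminaphtone 3 h replicate 1. It was 2 without control 6 h replicate 1 or 3 or aminaphtone 6 h replicate 2, and 3 without aminaphtone 6 h replicate 1 or 3.

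Averaged over the 3 times, with 9 arrays per arm, TNFSF18 was 3.27-fold lower with aminaphtone (log2 -1.71, SE 0.182, adjusted p = 0.000334), and EDN1 1.89-fold lower (log2 -0.92, SE 0.103, adjusted p = 0.000334). IGFL1 was 2.18-fold lower (log2 -1.13, SE 0.139, adjusted p = 0.000546), and EBI3, S100A3 and CCL22 1.86-fold, 1.88-fold and 1.81-fold lower (each adjusted p = 0.000546). TNFRSF11B, the gene of osteoprotegerin, was 1.88-fold lower (adjusted p = 0.0154), and IL1B 1.61-fold lower (log2 -0.69, SE 0.149, adjusted p = 0.0407). HMOX1 was lower as well (log2 difference -0.44, SE 0.0878, adjusted p = 0.0239), and PDGFB, a platelet-derived growth factor, fell 1.53-fold (adjusted p = 0.0239). MYLIP was 1.69-fold higher (log2 0.76, SE 0.0834, adjusted p = 0.000334) and MEGF9 1.69-fold (adjusted p = 0.013). PRKCA, protein kinase C alpha, was 1.53-fold higher (adjusted p = 0.0239), and MERTK 1.45-fold higher (adjusted p = 0.0058). GCLM, which acts in glutathione synthesis, was 1.48-fold higher (adjusted p = 0.0463), and BCL2L11, the gene of the pro-apoptotic protein BIM, 1.37-fold higher (adjusted p = 0.0118). Of the inflammatory genes fixed in advance, CCL2 (log2 -0.30, adjusted p = 0.164), IL6 (-0.13, adjusted p = 0.352), CXCL8 (-0.05, adjusted p = 0.68) and ICAM1 (-0.02, adjusted p = 0.85) did not pass. Neither PTGS2 (0.09, adjusted p = 0.573), NFKBIA (0.07, adjusted p = 0.441) nor SELE (0.40, adjusted p = 0.068) passed, nor did TGFB1 (-0.12, adjusted p = 0.506), VEGFA (-0.37, adjusted p = 0.116) or NQO1 (0.14, adjusted p = 0.231).

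Cytokine and chemokine genes were lower on average, 3 of 22 over all genes tested (IL1B, CXCL6 and IL32) and 10 lower against 1 higher adjusted over the list alone (median log2 -0.18, camera adjusted p = 4.91e-05; adjusted p = 0.732 with an estimated correlation). Of the 31 hypoxia and glycolysis genes, 6 were lower over all genes tested, among them DDIT4, an inhibitor of mTORC1, 1.61-fold, and 10 adjusted over the list alone (median -0.10, adjusted p = 2e-05; adjusted p = 0.515 with an estimated correlation; fry adjusted p = 0.0151). In the unfolded protein response list, DDIT3, the stress factor CHOP, and HERPUD1 rose 1.31-fold and 1.23-fold over all genes tested, and 3 of 19 rose adjusted over the list alone (median 0.08, adjusted p = 0.0104; adjusted p = 0.515 with an estimated correlation). That list lost its call without control 1 h replicate 1 (adjusted p = 0.0571) and with the stricter filter (0.0808).

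The average called 131 transcript clusters, 67 higher and 64 lower, or 51 higher and 80 lower with each array centred on its median. With a block within times 500 were higher and 235 lower, and with the array gradient as a covariate 325 and 183. Of the 45 named and called genes, 19 passed without every array in turn, including TNFSF18, EDN1, MYLIP, IGFL1, EBI3, S100A3, CCL22, TNFRSF11B, MEGF9, MERTK and BCL2L11. IL1B, HMOX1, PDGFB, PRKCA, GCLM, DDIT3, HERPUD1 and DDIT4 did not, with highest adjusted p-values of 0.109, 0.0734, 0.0734, 0.0677, 0.122, 0.111, 0.111 and 0.0667. In the fit with the array gradient and the fit without the 1 h arrays, whose average covers 3 and 6 h, 31 of the 45 kept their calls, and BCL2L11, PDGFB, GCLM, DDIT3, HERPUD1 and DDIT4 lost theirs without the 1 h arrays. Without both control 1 h replicates 2 and 3 the count was 84, with 60 of the 131 among them. GCLM also lost its call with quantile normalization applied again, and HERPUD1 with that, the stricter filter, arrays centred on their medians and a trended, robust variance. The count was 3444 without control 1 h replicate 1, and 50, 82 and 84 without aminaphtone 1 h replicates 1, 2 and 3. It was 76 without control 3 h replicate 2, and 72 and 59 without aminaphtone 3 h replicates 1 and 3. It was 51, 76 and 85 without control 6 h replicates 1, 2 and 3, and 85, 56 and 51 without aminaphtone 6 h replicates 1, 2 and 3.

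The interaction asked whether the effect of aminaphtone differed between the times. It did for BNIP3, with log2 differences of 0.15, -0.16 and -1.34 at 1, 3 and 6 h (SE 0.129 each, n = 3 per group, adjusted p = 0.00457), and for PFKFB4, at -0.08, 0.06 and -1.42 (SE 0.161, adjusted p = 0.0248). PRDM1 stood at -1.30, -0.06 and -0.01 (SE 0.122, adjusted p = 0.00457), and MIDEAS at -0.89, 0.26 and 0.11 (SE 0.118, adjusted p = 0.0183). MYLIP stood at 1.5, 0.61 and 0.17 (SE 0.144, adjusted p = 0.0489), and DIPK2A at 0.63, 0.23 and -0.69 (SE 0.111, adjusted p = 0.00457). FOS, at 1.09, 0.02 and 0.11, did not pass (adjusted p = 0.179), nor did PDK1, at 0.52, -0.25 and -1.24 (adjusted p = 0.104). The effect on the hypoxia and glycolysis list was lower at 6 h than at 3 h, with 30 of 31 genes in that direction, 2 past the threshold over all genes tested and 8 adjusted over the list alone (median -0.36, camera adjusted p = 5.79e-30; 0.0026 with an estimated correlation). The effect on the G2/M list was lower at 3 h than at 1 h, with 17 of 26 genes past the threshold adjusted over the list alone (median -0.89, adjusted p = 4.65e-15; adjusted p = 0.125 with an estimated correlation).

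**Figure D4:**
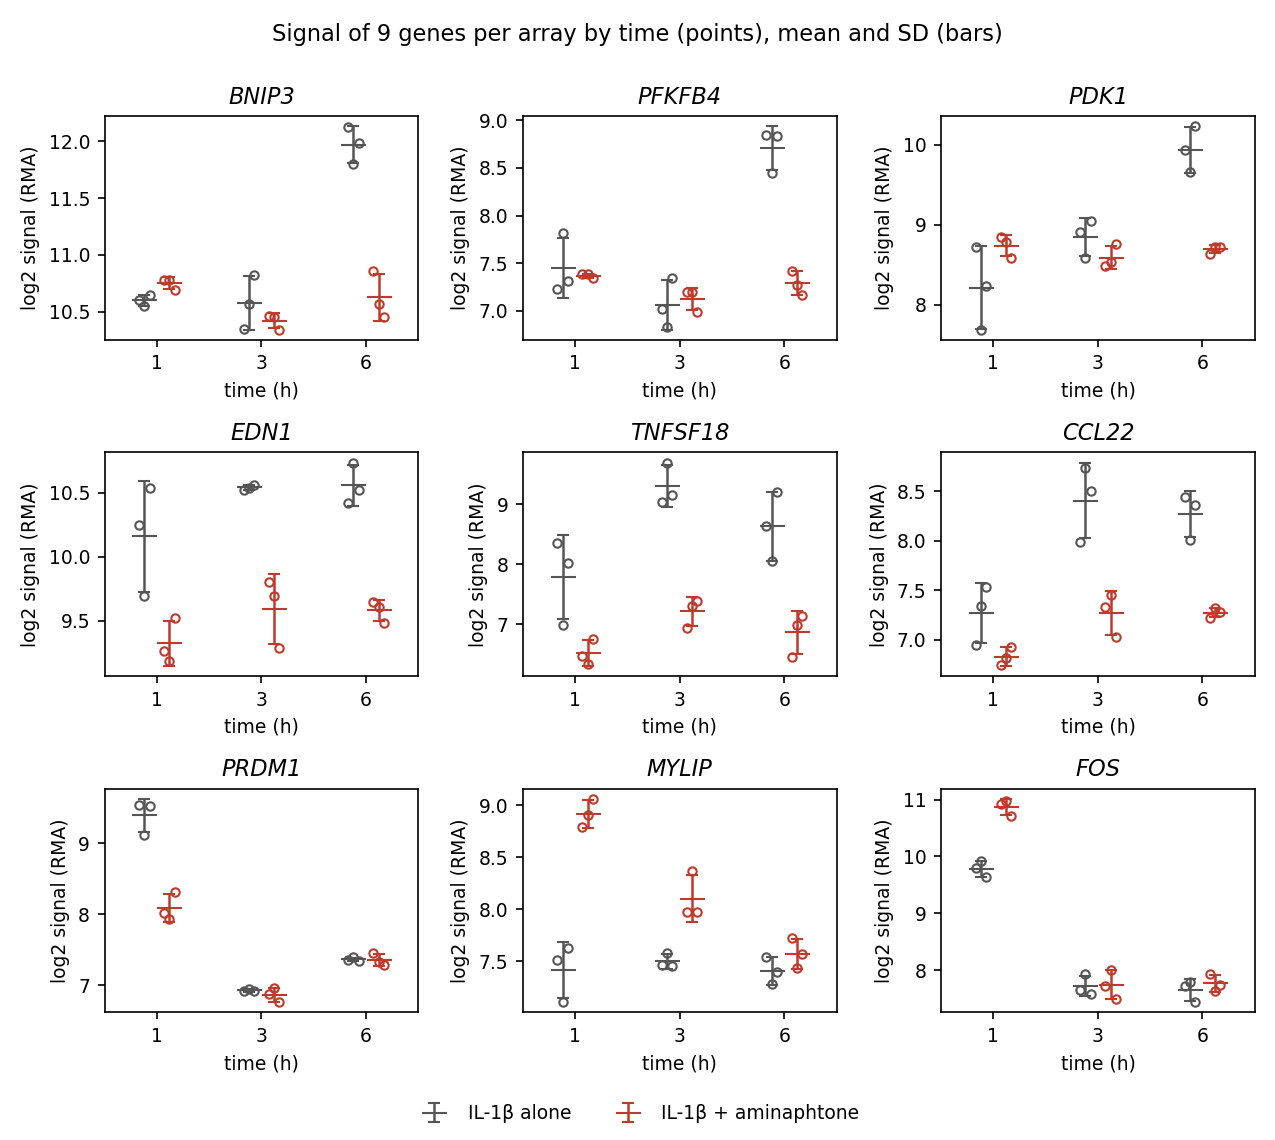
Log2 signal (y axes, RMA) of 9 genes by time in h (x axes), with 1 point per array, and the mean and SD of 3 arrays as bars, in cells with IL-1β alone and with IL-1β and aminaphtone. BNIP3 at 6 h averages 10.6 with aminaphtone and 12 without, and PRDM1 at 1 h averages 8.09 and 9.39.

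Those 6 genes were all that the interaction called, with 1458 transcript clusters at an unadjusted p under 0.05. Among 100 splits of the same arrays that part all pairs of equal number, 7, the real one included, called as many. With the block within times 8 called as many as the real split, so chance is not excluded for the count. The count was 2995 without control 1 h replicate 1, and 3 without control 1 h replicate 3, aminaphtone 1 h replicate 1, aminaphtone 1 h replicate 2 or aminaphtone 3 h replicate 1. PFKFB4 lost its call with a block within times (adjusted p = 0.0588), a fit that called 11, and PFKFB4, MIDEAS and MYLIP with a block for the replicate number over all groups (0.0633, 0.0523 and 0.0827), a fit that called 3. MYLIP also lost its call with no filter (0.0516), the stricter filter (0.0523), all transcript clusters (0.0714) and quantile normalization applied again (0.0884). BNIP3, DIPK2A and PRDM1 passed without every array in turn (highest adjusted p = 0.0384), whereas MIDEAS, PFKFB4 and MYLIP reached 0.109, 0.183 and 0.209. Without both control 1 h replicates 2 and 3, MIDEAS and MYLIP lost their calls (adjusted p = 0.228 and 0.224).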

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

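Of the tests in this part, those of the gradient through the other groups and along gene length, both tests of the hypoxia pattern, and the requirement that the paired fit give the same answer for the G2/M genes at 1 h were chosen after the result was seen.

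The effect of aminaphtone differed between times for 6 transcript clusters by the interaction test in limma without a block: BNIP3, DIPK2A and PRDM1 (each adjusted p = 0.00457), MIDEAS (adjusted p = 0.0183), PFKFB4 (adjusted p = 0.0248) and MYLIP (adjusted p = 0.0489). Chance is not excluded for this count, by the splits given under other observations. For the hypoxia and glycolysis list the difference between the effects at 6 and 3 h had adjusted p = 0.0026 with an estimated correlation. Among the 7807 transcript clusters without a gene annotation, which the comparisons of the report do not use, 1 was lower with aminaphtone at 6 h and 13 differed on average (4 higher and 9 lower). In the controls 156 of them differed between 1 and 3 h (85 higher and 71 lower), 489 between 1 and 6 h (284 higher and 205 lower) and 5 between 3 and 6 h (2 higher and 3 lower).

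The 1 h control arrays stood apart from each other, with scores of -20.4, 68.7 and 30.3 on a component that holds 59.9% of the residual variance. Control 1 h replicate 1, at -20.4, lay within the range of the 1 h aminaphtone arrays (-27.2 to -6.42). Without it the count at 1 h went from 14 to 8516. A wrong treatment label of this array was not tested. A wrong time label of control 1 h replicate 2 is argued against, since its immediate early genes lay -0.0723 of the way from the other 1 h arrays to the 3 h arrays (SD of the others 0.0726). The same gradient was found among the other arrays, with a correlation across genes of 0.837, and its loadings followed gene length (Spearman correlation across genes -0.389, and -0.331 from the other 15 arrays). A technical gradient related to gene length, such as from RNA quality or labelling, may contribute to the spread, as a hypothesis. Transcript length was not tested. GC content was not tested, and a difference between the cultures stays open, as the design gives no group within the 1 h controls.

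Hypoxia and glycolysis genes were lower with aminaphtone at 6 h, by a mean log2 difference of -0.494 over the list (SE 0.058; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays can give). With the gradient as a covariate the difference was -0.49 (SE 0.0522), which argues against the gradient as its cause. A delay common to the whole time course in treated cultures is argued against too: the difference of control minus treated at 6 h, which includes what was already present at 3 h, made up 1.2 of the control change between 3 and 6 h for this list, 0.135 for cholesterol synthesis and -0.333 for S phase, a lead of 1.06 (0.951 to 1.27 with 1 array left out). Between 3 and 6 h the list moved by 0.414 in the controls and -0.0514 in treated cells (SE 0.058 each), against -0.603 and -0.524 for cholesterol synthesis (SE 0.0993 each), -0.292 and -0.281 for S phase (SE 0.0544 each), 0.313 and 0.38 for G2/M (SE 0.158 each), 0.153 and 0.0155 for the unfolded protein response (SE 0.0596 each) and 0.17 and 0.0367 for TGF-β and matrix (SE 0.0581 each), so a delay limited to some of the rising lists stays open. An effect of aminaphtone on the induction of these genes is a candidate explanation, as a hypothesis found and tested on the same data, and differences between cultures in oxygen or density were not tested.

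G2/M genes were higher with aminaphtone at 1 h and lower at 3 and 6 h, by mean log2 differences of 0.591, -0.314 and -0.247 (SE 0.158 each; exact two-sided permutation p = 0.1, 0.1 and 0.2). With the gradient as a covariate the difference at 1 h was 0.341 (SE 0.14), and in the paired fit it went from 0.591 to 0.417 (SE 0.0965). The gradient is thus argued against as the whole of the difference. The SEs leave open whether it accounts for part. At 3 and 6 h the values with the gradient were -0.311 and -0.265 (SE 0.117 each), close to those without it. A change in the share of dividing cells, or cultures that differed before treatment, may lie behind the pattern, and neither was tested. Averaged over the times the list did not pass (camera adjusted p = 0.834), and none of its genes passed over all genes tested at 1, 3 or 6 h.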

How the results depend on the processing

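Fits without the 1 h arrays, without both control 1 h replicates 2 and 3, with the gradient as a covariate, and with identical rows counted once were chosen after the data were seen; the others were set before. The counts of transcript clusters stayed within 1.5 times their reported values with no filter on the mean, with quantile normalization applied again, with arrays centred on their medians and with identical rows counted once. The hypoxia and glycolysis list at 6 h kept its direction and its call in each of the alternatives run for it, those added later included (with 1 array left out, adjusted p = 1.7e-41 to 2.44e-25). With pairs as a block within times, the count at 1 h changed as the report gives. The heat shock list at 1 h lost its call (camera adjusted p = 0.0532), as did the TGF-β and matrix list on average (0.0816). No other list lost its call with that block. Where a count changed and the alternative's smaller number of arrays or genes does not account for it, the cause was not tested.

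With 1 array left out in turn, the count ranged from 6 to 8516 at 1 h, 0 to 48 at 3 h, 2 to 38 at 6 h, 50 to 3444 for the average and 3 to 2995 for the interaction. In the controls it ranged from 988 to 5719 between 1 and 3 h, 2586 to 7083 between 1 and 6 h and 16 to 309 between 3 and 6 h. In the order 1 h, 3 h, 6 h, average, controls 3 against 1 h, 6 against 1 h and 6 against 3 h, and interaction, array weights gave 11317, 727, 7460, 8852, 9640, 11742, 3713 and 9747, with weights of 0.0747 to 51.9 from a calculation that did not converge. With only the arrays compared, limma called 0 at 1 h, 1 at 3 h, 70 at 6 h (24 higher and 46 lower), and 228, 1088 and 166 in the controls in the same order. Single-gene tests without shared variance called 0, 0 and 1, and 0, 40 and 0 in the controls. Blocks within times gave 2465 at 1 h, 10 at 3 h, 26 at 6 h, 735 for the average (500 higher and 235 lower) and 11 for the interaction, and a block for the replicate number over all groups gave 3 for the interaction and 2292 between 1 and 3 h in the controls (916 higher and 1376 lower). The stricter filter gave 87 for the average, all transcript clusters gave 3 at 3 h, a trended robust variance gave 3 at 3 h, and a threshold of 1.5-fold gave 24 for the average and 2635 between 1 and 6 h.

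Without the 1 h arrays the count was 35 at 3 h, 32 at 6 h, 274 for the average, there of 3 and 6 h, and 276 between 3 and 6 h in the controls. With the gradient it was 359 at 3 h, 133 at 6 h (32 higher and 101 lower), 508 for the average (325 higher and 183 lower), 3292 between 1 and 3 h and 1208 between 3 and 6 h in the controls, and 17 for the interaction. Without both control 1 h replicates 2 and 3, which leaves that group with 1 array assumed to vary as the others do, it was 6 at 1 h, 86 at 3 h, 54 at 6 h, 84 for the average, 2333 between 1 and 6 h and 441 between 3 and 6 h. Centring the arrays changed the split between 1 and 3 h in the controls from 759 higher and 1261 lower to 956 and 969, and between 1 and 6 h from 1783 and 2402 to 2102 and 2059; quantile normalization applied again gave 868 and 1176 between 1 and 3 h.

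Some lists turned direction. Without the 1 h arrays the average covers 3 and 6 h, at both of which the S phase and G2/M lists had negative mean differences and at 1 h positive ones, so both turned to lower (adjusted p = 0.0231 and 3.71e-08). For the other turns the cause was not tested. With the gradient the adhesion list (adjusted p = 0.0018) and zinc finger list (0.369) at 1 h and the histone list on average (0.0154) turned. Without control 1 h replicate 2 the histone list between 1 and 3 h turned (0.0429, range with 1 array left out 0.0381 to 0.774), without control 3 h replicate 1 the small nuclear and nucleolar RNAs at 3 h (4.68e-05, range 5.39e-25 to 0.996) and between 1 and 3 h in the controls (0.0115, range 3.81e-09 to 0.96), without control 3 h replicate 2 the histone list at 3 h (0.816, range 1.33e-08 to 0.816), and without aminaphtone 3 h replicate 2 the immediate early list at 3 h (0.666, range 8.65e-07 to 0.673). With an estimated correlation 58 list results lost their call, and with fry 40 lost and 10 gained one. For arrays, genes with signals near the background, here those under the filter, cannot be compared.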

Other observations

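The hypothesis on the likeness of the 3 and 6 h differences in this part was noticed in the data, and its value was known before its test was run; the counts of other splits were planned, and those of splits that part all pairs of equal number were added after the results were seen.

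Genes of small nuclear and nucleolar RNAs, which guide the processing of other RNAs, had higher values with aminaphtone at 6 h in 133 of 149 (median log2 0.22, camera adjusted p = 4.33e-18; adjusted p = 0.686 with an estimated correlation), with none past the threshold over all genes tested or adjusted over the list alone. At 1 h the same list was lower (median -0.25, adjusted p = 0.00815; adjusted p = 0.878 with an estimated correlation), a call lost without control 1 h replicate 1 (adjusted p = 0.123) or aminaphtone 1 h replicate 2 (0.107). In the controls histone genes went down between 1 and 6 h, 22 of 55 over all genes tested and 25 adjusted over the list alone (median -0.34, adjusted p = 1.62e-05; adjusted p = 0.606 with an estimated correlation). S phase genes went down over the same interval, 13 of 26 over all genes tested and adjusted over the list alone (median -0.43, adjusted p = 0.000909; adjusted p = 0.412 with an estimated correlation). Zinc finger genes had higher values with aminaphtone at 1 h, 258 of 384 (median 0.25, adjusted p = 9.17e-05; adjusted p = 0.773 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.053), and the direction turned with the array gradient as a covariate (adjusted p = 0.369).

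Endothelial marker genes had lower values with aminaphtone on average in all 11 members above the filter (median log2 -0.15, camera adjusted p = 0.00234, or 0.753 with an estimated correlation). None passed over all genes tested, 1 was lower adjusted over the list alone, and CDH5, the gene of VE-cadherin, stood at -0.30 (adjusted p = 0.0634). The markers of each cell type spread widely in signal, and signals of different transcript clusters are not on a common scale. From the lowest to the highest member, the endothelial markers ran from EMCN to ENG (percentiles 6 and 79.4 of annotated transcript clusters), and the urothelial and epithelial markers from KRT20 to KRT8 (15.7 and 98.9). The fibroblast and mesenchymal markers ran from LUM to VIM (0.518 and 99.1), and the leukocyte markers from PTPRC to CD68 (1.51 and 70.7). Of 18 endothelial markers 7 lay under the filter (PECAM1, VWF, KDR, TEK, ERG, EMCN and MMRN1). Of 19 urothelial and epithelial markers 1 did (KRT20), as did 5 of 16 fibroblast and 8 of 16 leukocyte markers. In the controls all 18 urothelial and epithelial markers tested had negative differences between 1 and 6 h, with 5 lower over all genes tested and 7 adjusted over the list alone (adjusted p = 0.00513; adjusted p = 0.588 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.0979) and with the array gradient as a covariate (0.124).

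Averaged over the times, camera gave an adjusted p of 0.275 for NF-κB targets, 0.39 for IL-1 receptor signalling, 0.76 for adhesion molecules, 0.194 for haemostasis, 0.142 for angiogenesis, 0.76 for immediate early genes, 0.204 for NRF2 targets, 0.39 for antioxidant enzymes, 0.718 for aryl hydrocarbon receptor targets and 0.718 for the ATF4 list. It gave 0.216 for heat shock, 0.204 for cholesterol synthesis, 0.514 for S phase, 0.597 for p53 targets, 0.308 for the interferon response, 0.216 for urothelial and epithelial markers, 0.275 for fibroblast markers, 0.275 for leukocyte markers, 0.26 for small nuclear and nucleolar RNAs, 0.962 for histones and 0.514 for ribosomal proteins. For junction genes (median 0.01, mean 0.03, adjusted p = 0.925) the test pointed down, and for apoptosis regulators (median -0.00433, mean 0.0233, adjusted p = 0.857) it pointed up. The TGF-β and matrix list (1 of 36 higher and 5 lower over all genes tested, 1 and 6 adjusted over the list alone; adjusted p = 0.0488) and the microRNA list (adjusted p = 0.0488) passed, both with adjusted p = 0.753 with an estimated correlation, and kept their calls without 7 and 10 of the 18 arrays in turn (highest adjusted p = 0.143 and 0.238). Both also lost them with no filter, with the stricter filter, with quantile normalization applied again, without the 1 h arrays (an average over 3 and 6 h) and with the array gradient as a covariate, and the TGF-β and matrix list with the block within times (adjusted p = 0.0816). The zinc finger list passed on average (2 of 384 higher over all genes tested, adjusted p = 2e-05; adjusted p = 0.749 with an estimated correlation), a call lost with the array gradient as a covariate (adjusted p = 0.159).

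Across 13805 genes the differences with aminaphtone at 3 h and at 6 h correlated at 0.566 (Spearman 0.525), those at 1 and 3 h at 0.0298 and those at 1 and 6 h at 0.134; these are correlations across genes, which are not independent replicates. A response shared by the later times may lie behind the first value, as a hypothesis: 4 of 100 combinations of splits of the 3 h and 6 h arrays, the real one included, gave a correlation as large in size, with 0.624 the highest of the others, and the value was 0.578 with the gradient as a covariate.

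Other splits of the same arrays were counted for each comparison. For the average, 131 transcript clusters passed in the real split and at most 14 in the other 99 of 100 drawn, 1 of 100 as large. Since equal numbers went together at 1 h, 100 splits that part all pairs of equal number, as the real one does, were counted too. Of these, 1 of 100, the real one, gave as many (highest other 16). With the block within times 2 of 100 did (real 735, highest other 917), so another split called more than the real one. Chance is therefore unlikely for the count of the average in both fits, and not excluded. For the interaction 6 passed, and 4 of 100 splits gave as many, the real one included (highest other 24). Among splits that part all pairs 7 of 100 did (highest other 64), and 8 of 100 with the block within times (real 11, highest other 304), so chance is not excluded for the count of the interaction; the splits with 64 and 304 point to a structure of the samples. For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real and highest other counts were 14 and 3433 at 1 h, 6 and 0 at 3 h, 17 and 0 at 6 h, 2020 and 3934 between 1 and 3 h in the controls, 4185 and 2 between 1 and 6 h, and 81 and 0 between 3 and 6 h. The splits with 3433 and with 1759 at 1 h, which put control replicate 1 with 2 treated arrays, and the split with 3934, which joins it with 3 h replicates 1 and 3, point to a structure of the samples. At 1 h, where arrays of equal number went together, the real split parts all 3 pairs. The other splits that do so gave 0, and those with 3433 and 1759 part 1 pair.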
